A study of Mus musculus with 12 samples.

How the data were processed

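RNA was sequenced from primordial germ cells, the embryonic precursors of sperm and eggs, of C57BL/6 mouse embryos at stage E12.5. Each library was made from 1000 cells, per the labels' protocols: the cells were lysed in a small volume, cDNA was synthesised in the same tube from mRNA, and sequencing libraries were prepared with a transposase-based kit. The submitters' processing notes name FastQC 0.11.9, STAR 2.5.3a, Cufflinks 2.2.1 and the mouse genome build mm10, without saying what each was used for. How reads were counted, which annotation was used and whether strand was taken into account are not given in the sources used here.

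The authors deposited 2 tables for the whole series, both with 1 row per gene symbol. One has 12 columns whose names end in FPKM, per the file headers. The other is deposited as raw counts and also has 12 columns. Of its 200688 values, 11312, or 5.6%, are not whole numbers, so they are not plain read counts. Its gene rows differ in the number of values they hold, with no mark for a missing value, so a short row read by position can place values under the wrong column. Another row repeats the header's first word, holds no value and was left out. In both tables the columns carry code names, a letter followed by a number, and none of these names occurs in the title, description or characteristics of any of the 12 samples. A search of all sample labels for the 12 code names of each table found 0 matches. The 24 columns of the 2 tables could therefore not be assigned to samples or groups from the labels. The columns were not assigned by their order, which would be a guess. Levels of Terc, X-linked or Y-linked genes were not used either, because such levels were planned as checks of the labels. None of the 24 columns was used as a measurement, and no depth, expression level, fold change or p-value is reported.

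What was computed here, with Python 3.11.15, is limited to the structure and format of the tables. It covers the number of gene rows, the number of values held by each row and the number of values that are not whole. Column names were searched for in the sample labels. Gene symbols were matched to the gene lists described below and to the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. A later match used RefSeq symbols. Samples were grouped by genotype and sex from their titles. Before the data were examined, 6 comparisons and 34 gene lists were fixed, with alternatives in normalization, filtering, test and left-out libraries. Of the 34 lists, 33 have at least 1 symbol in the tables. The list of mitochondrially encoded genes, defined by a symbol pattern, has none. Only symbols that fit this pattern were sought, so such genes under other names would have been missed. None of these comparisons or alternatives was run.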

Results

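The series was designed to compare the transcriptomes of primordial germ cells with short telomeres and of wild-type germ cells, in both sexes. The samples other than wild type are labelled Terc-/- in their titles, and their telomere length was not examined here. Terc encodes the RNA component of telomerase, the template from which the enzyme adds telomeric repeats. The 12 libraries, each of 1000 cells taken at stage E12.5, fall by their titles into 4 groups: wild-type male, Terc-/- male, wild-type female and Terc-/- female, with 3 libraries in each. The labels do not say whether the libraries of a group came from separate embryos or litters.

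The design implies a comparison of Terc-/- with wild type in males, the same comparison in females, a test of whether the genotype effect differs between the sexes, and a comparison of females with males within each genotype. None of these comparisons was made here. The columns of both deposited tables carry code names that match no sample label. The value of a gene in a column could therefore not be assigned to a genotype or a sex from the labels, and no other means was used. Levels, errors and differences between the 4 groups are not reported for any gene.

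The 2 tables list the same 25170 gene symbols, of which 24308, or 96.6%, are gene names in the GENCODE M21 annotation. Terc, the targeted gene, is listed in both tables. In GRCm38 it lies on the minus strand of chromosome 3, from 96414437 to 96414859, and is annotated as a non-coding RNA gene. Its level in the Terc-/- libraries, the first check of the labels, was not determined.

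In the FPKM table all 25170 gene rows hold 12 values. In the table of counts, 14258 gene rows, or 56.6%, hold 12 values, 4038 hold between 1 and 11 values and 6874 hold none. A row with fewer than 12 values has no empty cells to mark the missing places, so read by position some of its values can fall under the wrong column. Whether such rows can be realigned against the complete FPKM table was not tested. The rows with all 12 values include Terc and all 35 listed targets of p53, the transcription factor that responds to DNA damage. They also include all 24 telomere maintenance genes that the tables list, from a planned list of 25 symbols. Here and below, listed symbols are those that occur in the tables. Full coverage is not particular to these lists: 39 of 39 proliferation symbols and 84 of 84 cytosolic ribosome symbols also have complete rows. A complete row means only that 12 values are present, and whether a gene was detected in each library was not examined. Complete rows are also held by 8 of 9 listed Y-linked symbols, although the series includes female libraries. Among early meiotic genes 39 of 42 listed symbols have complete rows, and among germ cell identity genes 33 of 34. Coverage was lower than in these lists for 12 of 18 retinoic acid response symbols and 24 of 39 interferon response symbols with complete rows. Both shares are still above the 56.6% found over all gene rows. Complete rows were held by 3 of 20 symbols of the 2-cell-like state, which is below 56.6%. That is the lowest share among the 33 lists with a listed symbol. For other cell types of the fetal gonad, complete rows were held by 11 of 17 pre-granulosa symbols, 18 of 22 Sertoli symbols, 11 of 13 steroidogenic symbols, 17 of 20 mesenchymal symbols, 9 of 16 endothelial symbols, 16 of 16 macrophage symbols, 9 of 15 erythroid symbols and 11 of 13 coelomic epithelial symbols. Coverage was not compared between lists by a test, and why rows are incomplete was not tested. These shares describe the layout of the table of counts. They are not a measure of expression or of which cell types were present.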

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

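The titles number the libraries of each group, but the labels do not say that equal numbers in different groups share a litter. Pairs were therefore not defined by the labels. No paired analysis was possible because the columns also carry no replicate number given in the labels and could not be matched to samples. For the same reason none of the alternatives planned before the data were examined was run: other normalization factors, other filters on low counts, other tests, the FPKM table in place of counts, and leaving out each library in turn. As deposited, 14258 gene rows of the table of counts hold all 12 values, and realignment of the shorter rows was not tried.

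1 alternative was chosen after seeing the data. With RefSeq gene symbols of GRCm38.p6 in place of GENCODE M21, 24976 of the 25170 listed symbols were found in the annotation, against 24308. This count concerns the names of the rows only and answers no comparison of the design.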
